A study of Escherichia coli with 12 samples.

How the data were processed

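By their labels the samples were cultures of Escherichia coli K-12 MG1655 in which the fis gene, which encodes the nucleoid protein Fis, was interrupted by a kanamycin resistance cassette. Cells grew in LB at 37 °C with shaking and were taken at 90, 150, 240 and 360 minutes, which the labels call early, mid- and late logarithmic and early stationary phase. There were 3 replicates per time and 12 Affymetrix E. coli expression arrays in all. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays. No sample is labelled as having an intact fis gene, so every comparison is between growth times of samples labelled as the mutant.

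The deposited values are signal intensity per probe set on a linear scale, made by the authors with Affymetrix Microarray Analysis Suite 5.0 (MAS 5.0). The target of any scaling in that software is not given. Per the labels and the submitters' note, replicates 1 and 2 (8 arrays) were hybridised to an earlier Antisense array and remapped by the authors to the probe sets of the Antisense v2 array, on which replicate 3 (4 arrays) was run. These are called the older and the newer arrays, and array version cannot be separated from replicate 3. Of 7312 probe sets, 3744 had a value on all 12 arrays and 3568 only on the newer ones. Arrays give no depth, and precision is limited by their number.

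The 2% trimmed means of the deposited signals differed by more than 10% between arrays, so each array was scaled to the same 2% trimmed mean of 788.8. The rule set before the data were examined said that the trimmed mean runs over all probe sets. It was computed over the 3744 probe sets with a value on every array, a choice made after the files were seen and before any model was fitted. Counts under the literal wording, with each array's own probe sets, are given beside the results that they move. Scaled signals were transformed to log2(signal + 47.0), where 47.0 is the 10th percentile of the values of the genes tested. Where a group mean lies near or under 47.0 the size of a change depends on this pseudocount and is no measured fold, and a range "depending on the pseudocount" runs from its value at the 25th percentile to that at 1. Of 4398 annotated probe sets, 4286 stand for 1 MG1655 gene, 42 for several and 70 for none. Probe sets of 1 gene with a value on every array numbered 3641. Where a gene had several (22 genes), the probe set with the highest mean was used, which left 3617 genes tested, 57 of them with probes shared with other sequences. The gene table held 4651 genes. Coordinates are not given, because the genome build of the array is not stated.

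A linear model with the 4 time groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual and 5.45 prior degrees of freedom. Each 3-against-3 comparison used limma's moderated test, two-sided, with Benjamini-Hochberg (BH) adjustment over the 3617 genes and a call at an adjusted p under 0.05. A moderated F test covered any change over the 4 times. The whole span from 90 to 360 minutes is the sum of the 3 steps and not independent of them. Gene lists were tested with limma's camera at a preset correlation of 0.01, BH-adjusted over 30 lists and 4 comparisons (120 tests), and again with an estimated correlation and with fry. Lists needed at least 4 tested members. Camera compares a list's members with all other genes, so its call is no test of change by itself and can go with a median of the other sign. Values in text are log2 changes with the SE of the model, or means of scaled signal with the SD, for 3 arrays per time. In list results, "adjusted over the list alone" means BH within the list's members.

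The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. Named genes are fis and its operon partner dusB, the 10 largest rises and 10 largest falls of each step and the 5 and 5 largest of the whole span. These had to pass the test, to have all 3 arrays of one time above all 3 of the other, and to have a higher group mean above the median of all genes. Up to 4 members in the direction of each called list are added, as are all members of the lists of nucleoid proteins and topoisomerases, RNA polymerase and sigma factors, and ribosome hibernation. Probe sets of several genes are not named.

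The tests were tried on simulated data with 200 changed genes of 3617. At a log2 change of 2, the share recovered was 67.1% for 90 to 150 minutes, 74.2% for 150 to 240, 80.0% for 240 to 360 and 78.5% for 90 to 360. At a log2 change of 1 it was 25.8%, 12.3%, 20.6% and 12.3%. False calls made up 6.8%, 4.6%, 1.4% and 8.3% of the calls. Each comparison had a single simulated data set with the same spread and numbers of arrays, so differences between these shares reflect sampling. Simulated errors were independent between genes and between arrays, without replicate or array version effects, so the shares may not hold for the real arrays.

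Alternatives set beforehand were quantile normalization, centring each array on its median, values as deposited, a pseudocount of 1 or at the 25th percentile (129.5), a filter on dim probe sets, all probe sets except controls, a trended and robust variance, replicate number as a block, the 6 arrays of a comparison alone, and leaving out each array in turn. Alternatives chosen after seeing the data were array version as a block, the older arrays alone, the trimmed mean over each array's own probe sets, and the replicate block without the array labelled 150 minutes replicate 3. Tables were made in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. No array was left out of the model. Control and intergenic probe sets and those of other strains' genes were left out of the tests.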

Results

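The 12 arrays measured transcript levels in cells labelled as Fis-deficient at 90, 150, 240 and 360 minutes of growth, with 3 replicates per time. On the 3744 shared probe sets the trimmed mean of the deposited signal lay between 924.4 and 1117.6 on the 8 older arrays and between 296.9 and 540.7 on the 4 newer ones. The median SD of the log2 signal between replicates was 0.38 at 90, 0.45 at 150, 0.42 at 240 and 0.39 at 360 minutes. Pearson's r across genes, which are not independent replicates, was 0.831 to 0.940 between arrays of one time and 0.598 to 0.912 between arrays of different times. The first principal component held 44.3% of the variance and the second 13.8%. At most 7 of 3744 values were identical between any 2 arrays.

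**Figure D1:**
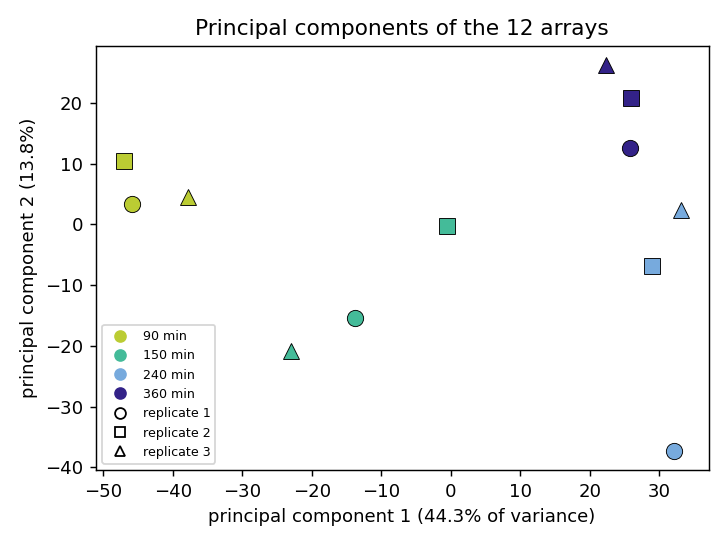
Scores of the 12 arrays on the first (44.3% of the variance) and second (13.8%) principal components of the log2 signal, in log2 units, coloured by time, with marker shape for the replicate. The array of 240 minutes replicate 1 lies lowest on the second component, at -37.3.

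The gene that the labels give as interrupted, fis (b3261), encodes a nucleoid protein that is abundant in wild-type cells early in growth. Its scaled signal was 112.6 to 492.3 on 11 arrays, at percentiles 22.8 to 62.1 of the genes of each array. On the array labelled 150 minutes replicate 3 it was 5697.2, at percentile 96.2. The deposited fis signal of that array was 2342.3, against 104.3 to 337.8 on the others. The fis change from 90 to 150 minutes did not pass limma's test (1.07, SE 0.87, adjusted p = 0.62, and -0.37 with adjusted p = 0.62 without that array). No array is labelled as from cells with an intact gene, and values without this array are given for calls that it ends and for list counts and medians that it moves by more than 1.5 times.

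The gene dusB (b3260), upstream of fis in the same operon, encodes a tRNA-dihydrouridine synthase. Its mean scaled signal was 11630 ± 1440 at 90 minutes, 4073 ± 2150 at 150, 1291 ± 143 at 240 and 861.9 ± 184 at 360 (SD, n = 3). From 90 to 360 minutes dusB fell by 3.70 on the log2 scale (SE 0.41, limma adjusted p = 4.2e-05), with -3.62 on the older and -3.84 on the newer arrays. The step from 90 to 150 minutes passed at -1.69 (adjusted p = 0.039, and 0.028 without the array labelled 150 minutes replicate 3). That call ended without any one of 9 of the 12 arrays (0.053 to 0.16). It held only with 150-minute replicate 3 or 240-minute replicate 1 or 3 left out. The step from 150 to 240 minutes passed at -1.44 (adjusted p = 0.047), but not with array version as a block (0.053) nor without any one array other than 150-minute replicate 2 (0.06 to 0.2, among them -1.13 with 0.15 without the array labelled 150 minutes replicate 3). The dusB call from 90 to 360 minutes held without each array.

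**Figure D2:**
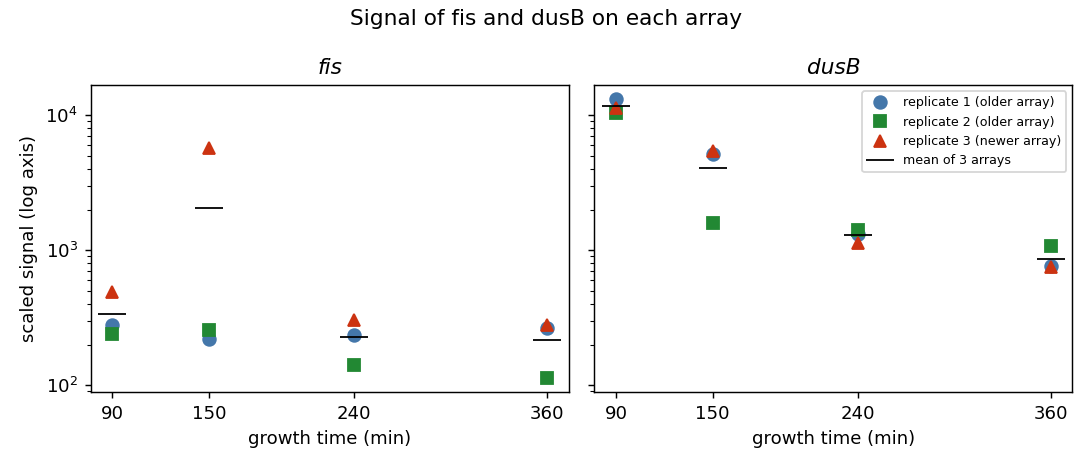
Scaled signal of fis and of dusB on each of the 12 arrays on a log axis, by time in minutes, with marker shape for the replicate (replicate 3 on the newer array version) and bars for the mean of the 3 arrays. The fis signal of the array labelled 150 minutes replicate 3 is 5697.2 and the other 11 lie between 112.6 and 492.3, while dusB goes from a mean of 11630 at 90 minutes to 861.9 at 360.

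The first comparison asks what changed between early and mid-logarithmic phase. The tryptophanase gene tnaA (b3708) rose from a scaled signal of 95.32 ± 75.4 at 90 minutes to 8607 ± 4460 at 150 (log2 5.90, SE 0.66), and its leader peptide gene tnaC rose by 5.94 (SE 0.80). The citrate synthase gene gltA rose by 3.13 (SE 0.38), and the galactose-binding protein gene mglB by 4.55 (SE 0.78). The flagellin gene fliC rose by 3.83 (SE 0.75, and by 3.01 without the array labelled 150 minutes replicate 3). Among the falls were yfhL, which encodes a ferredoxin-like protein (-2.69, SE 0.29), cspF of the cold shock protein family (-2.56, SE 0.32) and ndh, NADH dehydrogenase II (-2.39, SE 0.47). By limma 101 genes rose and 49 fell of 3617 (592 at an unadjusted p under 0.05), all at least 2-fold, while the median of all genes moved by 0.17. With array version as a block 104 rose and 62 fell, on the older arrays alone 112 and 24 (83 shared), and without the array labelled 150 minutes replicate 3, 104 and 50 (103 shared). The count of 150 became 6 without 90-minute replicate 1, 8 without 90-minute replicate 2, 22 without 150-minute replicate 1, 71 without 150-minute replicate 2, 90 without 360-minute replicate 1, 99 without 360-minute replicate 3 and 14 with only the 6 arrays compared. It was 56 with the trimmed mean over each array's own probe sets (55 shared), 58 with a pseudocount of 1 and 45 on values as deposited, and the share that rose, 67.3%, was 53.2% after quantile normalization, 44.2% after median centring and 88.9% as deposited. Of the 44 genes named for this step that passed, 5 passed without any one of the 12 arrays, namely tnaA, tnaC, gltA, cspF and yfhL.

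Lists that camera called upward from 90 to 150 minutes at the preset correlation include genes for motility, the tricarboxylic acid (TCA) cycle and the use of carbon sources. Of 52 flagella and chemotaxis genes, 12 rose and 0 fell (46 rose adjusted over the list alone), with a median of 1.96, or 1.65 on the older and 2.41 on the newer arrays. Without the array labelled 150 minutes replicate 3, 3 flagella genes rose, with a median of 1.40 (camera adjusted p = 3.26e-07). With each array left out in turn 0 to 24 rose, 0 without 90-minute replicate 1 or 2 and 1 without 150-minute replicate 1. Of 15 TCA cycle genes 10 rose (14 adjusted over the list alone), or 1 without 90-minute replicate 1 or 2 or 150-minute replicate 1, with a median of 2.27, or 2.71 on the older and 0.905 on the newer arrays. Besides gltA these include sdhA of succinate dehydrogenase (3.13), fumA, a fumarase (3.06), and mdh, malate dehydrogenase (3.02). Of 68 genes for sugars other than glucose and for glycerol 13 rose (22 adjusted over the list alone, 0 without 90-minute replicate 1 or 2), among them treB (3.67) and treC (3.43) for trehalose and galT for galactose (3.15), with a median of 0.964, or 1.40 on the older and 0.225 on the newer arrays. Of 22 genes of amino acid breakdown 5 rose (7 adjusted over the list alone, 1 without 90-minute replicate 1 or 2), with dadA and dadX of alanine breakdown at 3.29 and 2.77. Camera called these lists at adjusted p = 1.33e-20, 5.82e-14, 2.69e-11 and 3.9e-06. None held: adjusted p = 0.435, 0.283, 0.435 and 0.283 with an estimated correlation, while fry gave adjusted p = 0.0682, 0.00937, 0.0411 and 0.00937.

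The RpoS-dependent stress list (3 of 21 rose, 7 adjusted over the list alone, median 0.998) and the ribosome hibernation list (2 of 4 rose, 3 adjusted over the list alone, median 2.21) were called by camera at adjusted p = 1.59e-07 and 0.00103. Both had adjusted p = 0.283 with an estimated correlation, while fry gave adjusted p = 0.0122 and 0.0104. The hibernation members that rose were raiA (2.79, SE 0.52) and sra (2.15, SE 0.36), while rmf was at 2.27 (SE 0.77) and hpf at 0.36 (SE 0.37) without passing limma's test. With array version as a block rmf passed (adjusted p = 0.048), as it did without the array labelled 150 minutes replicate 3 (3.05, adjusted p = 0.04), where 3 hibernation genes rose. Without 90-minute replicate 1 or 2, 0 genes of either list rose, as did 0 of the hibernation list without 150-minute replicate 1 and 0 of the RpoS-dependent list without 150-minute replicate 2. Without 150-minute replicate 1, 1 RpoS-dependent gene rose. In the list of NADH dehydrogenase I and cytochrome bo oxidase 1 of 18 genes rose (1 adjusted over the list alone), nuoN (1.52, limma adjusted p = 0.10 without the array labelled 150 minutes replicate 3, a call that ended without any one of 9 of the 12 arrays), with a list median of 1.25 (camera adjusted p = 5.16e-06), or 0 genes and 0.968 (0.0252) without that array. That list had adjusted p = 0.565 with an estimated correlation. With 90-minute replicate 3 left out 10 of its genes rose and its median was 1.90, and without 90-minute replicate 2 it was 0.743. Phosphate starvation (1 of 29 rose, psiF at 1.68, or 0 without any one of 7 arrays, 1 adjusted over the list alone, median 0.468) and anaerobic respiration, hydrogenases and fermentation (1 of 61 rose and 1 fell, also adjusted over the list alone, median 0.46) passed camera at adjusted p = 0.0124 and 0.0161. Both had adjusted p = 0.665 with an estimated correlation. The phosphate call ended without 90-minute replicate 3 (adjusted p = 0.0627) or 150-minute replicate 2 (0.202, median 0.258). Its median was 0.695 on the older and -0.0352 on the newer arrays and 0.77 (adjusted p = 0.00164) without the array labelled 150 minutes replicate 3. The anaerobic call ended without the array labelled 150 minutes replicate 3 (0.112, with 2 up and 1 down) and on values as deposited (0.106). With each array left out in turn 0 to 4 anaerobic genes rose and 0 to 2 fell, with a median of 0.305 without 150-minute replicate 2.

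Camera called lists of the translation apparatus downward from 90 to 150 minutes at the preset correlation, with few single genes past limma's test. The calls of rpmH and prfC below ended without any one of 6 and 5 of the 12 arrays. Of 54 ribosomal protein genes 1 fell, rpmH (-1.22), and 0 adjusted over the list alone, with a median of -0.659 (camera adjusted p = 3.05e-12). The list had adjusted p = 0.435 with an estimated correlation and 0.224 with fry. Its median was -1.09 on the older but 0.123 on the newer arrays and -0.244 without 150-minute replicate 2. Of 9 translation factor genes 1 fell, prfC (-1.30), a peptide chain release factor, also 1 adjusted over the list alone, with a list median of -0.782 (camera adjusted p = 0.000219, or adjusted p = 0.25 with an estimated correlation), or -0.323 without 150-minute replicate 2. Of 28 iron acquisition genes 2 fell, exbD (-1.40) and fecA (-1.30), also 2 adjusted over the list alone, though neither passed limma without the array labelled 150 minutes replicate 3 (adjusted p = 0.052 and 0.082) and the calls ended without any one of 11 and 9 of the 12 arrays, and the list median was -0.255, or -0.103 without that array and -0.436 without 90-minute replicate 2 (camera adjusted p = 0.000926 and 0.00509, or adjusted p = 0.435 with an estimated correlation). Over all genes or adjusted over the list alone, no member of the lists of aminoacyl-tRNA synthetases (median -0.545), purine biosynthesis (-0.372), tRNA genes (-0.199) or heat shock chaperones and proteases (-0.256) passed limma. Camera gave these adjusted p = 1.5e-05, 0.00675, 0.0308 and 0.0482, or adjusted p = 0.283, 0.44, 0.756 and 0.699 with an estimated correlation. Without the array labelled 150 minutes replicate 3, 1 purine gene fell. The tRNA median was then 0.0159, with the list still called downward relative to the other genes (camera adjusted p = 0.0431). The purine call ended without 90-minute replicate 3 (0.143, median -0.0502) or 150-minute replicate 2 (0.0639). Its median was -0.236 without 150-minute replicate 1. The tRNA call ended without 90-minute replicate 1 (0.109, median -0.0435), 90-minute replicate 2 (0.677, median 0.22) or 150-minute replicate 1 (0.146, median -0.103), after quantile normalization (0.889) and after median centring (0.166). Its median was -0.508 on the older and 0.535 on the newer arrays, -0.739 without 90-minute replicate 3 and -0.387 without 150-minute replicate 2. The heat shock call ended without the array labelled 150 minutes replicate 3 (0.73, median 0.286), without 90-minute replicates 1 and 2 in turn (0.0677 and 0.122), 240-minute replicate 2 (0.0502) or 360-minute replicate 3 (0.0508), after quantile normalization (0.353) and as deposited (0.0607). The heat shock median was 0.141 on the older and -1.01 on the newer arrays and -0.62 without 150-minute replicate 2.

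The second comparison asks what changed between mid- and late logarithmic phase. The protein kinase gene yeaG (b1783), one of the RpoS-dependent list, rose from 201.8 ± 73.6 at 150 minutes to 4461 ± 1720 at 240 (log2 4.15, SE 0.36). The quinone oxidoreductase gene wrbA rose by 3.65 (SE 0.41), the periplasmic trehalase gene treA by 3.38 (SE 0.49) and osmE by 3.38 (SE 0.40). The acid chaperone genes hdeA and hdeB rose by 3.73 (SE 0.60) and 3.38 (SE 0.71), and gadB, a glutamate decarboxylase, rose from a mean of 31.51, by 2.80 to 4.89 depending on the pseudocount. The trehalose genes treC (-3.49, SE 0.68) and treB (-2.99, SE 0.67), which had risen in the first step, fell, as did sodA (-2.69, SE 0.49), manganese superoxide dismutase. By limma 193 genes rose and 99 fell (832 at an unadjusted p under 0.05), all at least 2-fold, while the median of all genes moved by -0.14. With array version as a block 212 rose and 119 fell, on the older arrays alone 85 and 24 (87 shared). Without the array labelled 150 minutes replicate 3, 138 rose and 69 fell (177 shared). The count of 292 became 184 without 150-minute replicate 1, 170 with only the 6 arrays compared and 206 with the trimmed mean over each array's own probe sets (200 shared). On values as deposited it was 111, of which 94.6% rose against 66.1%. Of the 50 genes named for this step that passed, 30 passed without any one of the 12 arrays.

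Of 21 RpoS-dependent stress genes 18 rose from 150 to 240 minutes (21 adjusted over the list alone), with a median of 2.57, or 2.34 on the older and 3.31 on the newer arrays. Camera called the list at adjusted p = 6.4e-25, and it had adjusted p = 0.0563 with an estimated correlation and 0.000101 with fry. Of 14 acid resistance genes 7 rose (7 adjusted over the list alone), with a median of 2.14 (camera adjusted p = 1.68e-06), or 1.11 on the older and 3.72 on the newer arrays. That list had adjusted p = 0.435 with an estimated correlation and 0.0695 with fry. Without the array labelled 150 minutes replicate 3, 3 acid resistance genes rose, with a median of 1.90 (camera adjusted p = 1.79e-05). Of the list 4 rose without 150-minute replicate 1 or 240-minute replicate 3, with a median of 1.31 without the latter. In the hibernation list 1 of 4 genes rose, sra (3.30, SE 0.36), or 3 adjusted over the list alone, while rmf was at 2.56 (SE 0.77) without passing, though it passed with array version as a block (limma adjusted p = 0.017), and camera gave adjusted p = 0.000658, or adjusted p = 0.283 with an estimated correlation. Of 16 genes of glycolysis and the glucose phosphotransferase system 2 rose, crr (1.12) and pfkB (1.53), though neither passed without the array labelled 150 minutes replicate 3 (limma adjusted p = 0.059 and 0.15). These calls ended without any one of 5 and 9 of the 12 arrays. That list had 3 genes up adjusted over the list alone and had a median of 0.702 (camera adjusted p = 0.000338, or adjusted p = 0.435 with an estimated correlation), or 0.443 with 0 genes up over all genes without 240-minute replicate 1. Of 61 anaerobic genes 4 rose (4 adjusted over the list alone), among them nirD (2.92) and nirB (2.29) of nitrite reductase and narI (1.36 to 2.44 depending on the pseudocount) of nitrate reductase (camera adjusted p = 0.00256, list median 0.265). That list had adjusted p = 0.665 with an estimated correlation, and its call ended without 240-minute replicate 1 (0.248, median -0.0599). The anaerobic median was 0.484 and 0.583 without 240-minute replicates 2 and 3. Of 68 sugar and glycerol genes 5 rose, including lamB (2.75, a call that ended without any one of 4 arrays), the maltoporin gene, and xylF (2.60) for xylose, and 2 fell, treB and treC, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00808, list median 0.476), and 1 to 12 rose with each array left out in turn (1 without 240-minute replicate 3 and 12 without 90-minute replicate 3). That list had adjusted p = 0.675 with an estimated correlation. None of the 14 genes for cysteine and sulfate passed limma (0 rose and 0 fell, also adjusted over the list alone, list median 0.764, or 1.41 on the older and -0.14 on the newer arrays, and 1.29 with 1 up without the array labelled 150 minutes replicate 3, or 3 up without 240-minute replicate 1). With each array left out in turn that median ran from 0.247 without 240-minute replicate 2 to 1.31 without 240-minute replicate 1. Their camera adjusted p was 0.047, or adjusted p = 0.695 with an estimated correlation, and the call ended with array version as a block (0.0519), under 3 other scalings (0.058 to 0.096) and without 90-minute replicate 3, 150-minute replicate 1 or 2, 240-minute replicate 2 or 3, or 360-minute replicate 3 (0.053 to 0.792).

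Of 54 ribosomal protein genes 26 fell from 150 to 240 minutes (38 adjusted over the list alone), with a median of -1.56, or -1.25 on the older and -1.98 on the newer arrays. Without the array labelled 150 minutes replicate 3, 10 fell, with a median of -1.25 (camera adjusted p = 2.94e-09). The count of 26 was 11 without 150-minute replicate 1, 14 without 240-minute replicate 1 and 43 without 150-minute replicate 2. Camera called the list at adjusted p = 6.73e-19, and it had adjusted p = 0.394 with an estimated correlation and 0.0236 with fry. Its largest falls, rplP (-2.69, SE 0.72), rpsQ (-2.60, SE 0.69), rpmC (-2.56, SE 0.67) and rpsT (-2.54, SE 0.57), did not pass limma without the array labelled 150 minutes replicate 3 (adjusted p = 0.11, 0.11, 0.11 and 0.06). These calls ended without any one of 3, 4, 3 and 1 of the 12 arrays. Of 9 ATP synthase genes 2 fell, atpI (-1.28) and atpF (-1.18), or 7 adjusted over the list alone, though neither passed limma over all genes without that array (adjusted p = 0.091 and 0.11). That list had a median of -1.28 (camera adjusted p = 0.00016, or adjusted p = 0.435 with an estimated correlation). Of 15 purine biosynthesis genes 1 fell, prs (-1.16, limma adjusted p = 0.074 without that array), or 7 adjusted over the list alone (list median -0.903, camera adjusted p = 0.000185, or adjusted p = 0.383 with an estimated correlation). Of 9 cold shock genes 2 fell, cspF (to a mean of 13.15, -1.45 to -4.62 depending on the pseudocount) and cspC (-1.60, limma adjusted p = 0.12 without that array), or 6 fell and 1 rose adjusted over the list alone, with a list median of -1.60 (camera adjusted p = 0.0056, or adjusted p = 0.45 with an estimated correlation). Of 28 iron genes 3 fell, fhuF (-1.74 to -3.26 depending on the pseudocount), exbB (-1.87) and exbD (-1.76), also 3 adjusted over the list alone (list median -0.535, or -0.342 without 150-minute replicate 2, camera adjusted p = 0.00126, or adjusted p = 0.435 with an estimated correlation). Of 47 tRNA genes 1 fell, lysW (-1.31, limma adjusted p = 0.095 without that array), and 0 adjusted over the list alone, with a list median of -0.743, or -0.465 without 150-minute replicate 2 (camera adjusted p = 0.000658, or adjusted p = 0.665 with an estimated correlation). With each array left out in turn 0 to 3 ATP synthase, 0 to 2 purine, 1 to 3 cold shock and 0 to 3 tRNA genes fell. The calls of atpI, atpF, cspC, lysW and prs ended without any one of 6, 7, 6, 7 and 4 of the 12 arrays.

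Of 52 flagella and chemotaxis genes 5 fell from 150 to 240 minutes (10 adjusted over the list alone), among them fliQ (-2.68, SE 0.52) and fliR (to a mean of 38.13, -1.85 to -3.78 depending on the pseudocount) of the flagellar export apparatus. The count of 5 was 14 without 150-minute replicate 2, 9 without 240-minute replicate 1 and 3 without 150-minute replicate 1 or 240-minute replicate 3. The list median was -1.04 (camera adjusted p = 0.00418), and the list had adjusted p = 0.756 with an estimated correlation and 0.489 with fry. On the older arrays alone camera called the list upward (adjusted p = 0.026) with a median of 0.021, against -2.67 on the newer arrays. The downward call ended without the array labelled 150 minutes replicate 3 (0.553, 3 down and 1 up, median -0.491) or 240-minute replicate 3 (0.214, median -0.451). Of 9 translation factor genes 2 fell, infA (-2.33) and prfC (-1.57), also 2 adjusted over the list alone, with a list median of -0.851 (camera adjusted p = 0.0109, or adjusted p = 0.351 with an estimated correlation). That call ended without the array labelled 150 minutes replicate 3 (0.136). No aminoacyl-tRNA synthetase gene passed, over all genes or adjusted over the list alone, and the list, with a median of -0.467, had a camera adjusted p of 0.0494, or adjusted p = 0.569 with an estimated correlation. Its call ended without any one of 90-minute replicates 1 and 3, 150-minute replicates 1 and 3, 240-minute replicates 2 and 3, and 360-minute replicates 2 and 3 (0.0518 to 0.328), after median centring (0.0568), as deposited (0.303) and with the trimmed mean over each array's own probe sets (0.052).

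The third comparison asks what changed on entry into early stationary phase. The ferric hydroxamate reductase gene fhuF (b4367) rose from 53.92 ± 33.7 at 240 minutes to 3275 ± 354 at 360 (log2 5.09, SE 0.47, or 4.23 to 6.11 depending on the pseudocount). The bacterioferritin-associated ferredoxin gene bfd rose by 3.95 (SE 0.54), exbD and exbB of the TonB energy system by 3.80 (SE 0.36) and 3.23 (SE 0.38), and entF, for enterobactin synthesis, by 3.28 (SE 0.42, or 2.35 to 4.77 depending on the pseudocount). The genes of iron superoxide dismutase, sodB (-3.78, SE 0.36), and of ferritin, ftnA (-3.57, SE 0.56), fell, while sodA rose by 2.78 (SE 0.49). The maltose genes malE (-4.39, SE 0.89), malK (to a mean of 30.52, -3.41 to -5.70 depending on the pseudocount) and lamB (-3.66, SE 0.72) fell, but these calls ended without any one of 4, 8 and 4 of the 12 arrays, and that of sodA ended without 1. By limma 30 genes rose and 28 fell (403 at an unadjusted p under 0.05), all at least 2-fold, while the median of all genes moved by 0.11. With array version as a block 29 rose and 21 fell, on the older arrays alone 15 and 12 (26 shared), and without the array labelled 150 minutes replicate 3, 33 and 30 (55 shared). The count of 58 became 33 and 37 without 90-minute replicates 1 and 2, 36 without 150-minute replicate 1, 32 and 29 without 240-minute replicates 1 and 2, 35, 19 and 27 without 360-minute replicates 1, 2 and 3, and 34 with only the 6 arrays compared. It was 29 with the trimmed mean over each array's own probe sets (29 shared), 28 with a pseudocount of 1 and 27 on values as deposited, and the share that rose, 51.7%, was 69.0% with each array's own probe sets and 25.9% as deposited. Of the 22 genes named for this step that passed, 14 passed without any one of the 12 arrays.

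Of 28 iron acquisition genes 14 rose from 240 to 360 minutes and 0 fell (26 rose adjusted over the list alone), with a median of 1.63, or 1.67 on the older and 1.58 on the newer arrays. Camera called the list at adjusted p = 5.47e-32 and also with an estimated correlation (adjusted p = 0.0318), the 1 call of 57 that held there. The count of 14 was 9 without 240-minute replicate 2 and 8 without 360-minute replicate 2. Of 52 flagella and chemotaxis genes 0 passed limma over all genes and 19 fell adjusted over the list alone, with a median of -1.46, or -1.62 on the older and -0.624 on the newer arrays, and -0.921 without 240-minute replicate 1. Camera called that list at adjusted p = 6.73e-19, and it had adjusted p = 0.435 with an estimated correlation. Over all genes 2 flagella genes fell without the array labelled 150 minutes replicate 3 and 9 without 150-minute replicate 2. Of 61 anaerobic genes 6 fell (7 adjusted over the list alone), including nirD (-3.47), nirB (-3.20), narK (-2.29) and narG (-2.07, limma adjusted p = 0.054 without the array labelled 150 minutes replicate 3), with a list median of -0.388, or -0.0719 without 240-minute replicate 1 and -0.227 without 360-minute replicate 3. The calls of narK and narG ended without any one of 9 and 10 of the 12 arrays. Of 68 sugar and glycerol genes 8 fell (16 adjusted over the list alone), including malE, malK and lamB and srlE for sorbitol (to a mean of 43.48, -1.78 to -4.06 depending on the pseudocount, a call that ended without either of 2 arrays), with a list median of -0.318, or -0.505 without 240-minute replicate 2, -0.523 without 360-minute replicate 1 and -0.171 without 360-minute replicate 3. With each array left out in turn 2 to 5 anaerobic genes and 0 to 8 sugar and glycerol genes fell, 0 of the latter without 360-minute replicate 2 or 3. Camera gave these lists adjusted p = 1.67e-07 and 3.2e-07, or adjusted p = 0.435 and 0.475 with an estimated correlation.

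Other lists passed camera from 240 to 360 minutes with 0 members past limma over all genes, where 1 cold shock gene rose and 1 amino acid breakdown gene fell adjusted over the list alone. Over all genes 1 amino acid breakdown gene rose and 3 fell without 240-minute replicate 3. Ribosomal proteins had a median of 0.546 (camera adjusted p = 2.25e-05, or adjusted p = 0.665 with an estimated correlation), or 0.326 without 360-minute replicate 2. The TCA cycle list had a median of -0.567 (camera adjusted p = 0.0109, or adjusted p = 0.665 with an estimated correlation), and its call ended without 240-minute replicate 2 (0.0988) or 360-minute replicate 3 (0.157, median -0.317). The cold shock list had a median of 1.09 (camera adjusted p = 0.0196, or adjusted p = 0.565 with an estimated correlation), and its call ended without 240-minute replicate 1 (0.13, median 0.637) or 360-minute replicate 3 (0.406, median 0.513). The cysteine and sulfate list had a median of -0.489 (camera adjusted p = 0.0161, or adjusted p = 0.665 with an estimated correlation), and its call ended without 240-minute replicate 2 (0.944, median 0.0935) or 360-minute replicate 3 (0.0581) and after quantile normalization (0.0686). Its median was -1.18 without 240-minute replicate 1 and -0.747 without 360-minute replicate 1. Amino acid breakdown had a median of -0.513 (camera adjusted p = 0.0248, or adjusted p = 0.549 with an estimated correlation), and its call ended without 240-minute replicate 1 (0.109, median -0.0577) or 360-minute replicate 3 (0.0611). Curli and type 1 fimbriae had a median of 0.551 (camera adjusted p = 0.0485, or adjusted p = 0.642 with an estimated correlation). Its call ended without 90-minute replicate 1, the array labelled 150 minutes replicate 3, 240-minute replicates 1 and 3, and 360-minute replicates 1, 2 and 3 in turn (0.0503 to 0.145), and after quantile normalization (0.111).

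The whole span compares early stationary with early logarithmic phase. The arginine breakdown gene astC (b1748) rose from 27.4 ± 15.4 at 90 minutes to 7054 ± 1290 at 360 (log2 6.58, SE 0.90, or 5.51 to 8.08 depending on the pseudocount). The ribosome-associated protein genes sra (b1480) and rmf rose by 6.07 (SE 0.36) and 5.61 (SE 0.77), ycaC by 5.13 to 6.61 depending on the pseudocount, and ytfQ, which encodes a sugar-binding protein, by 5.78 (SE 0.51). The DNA-binding protein gene dps rose by 4.77 (SE 0.55), with 5.00 on the older and 4.31 on the newer arrays. Among the falls were cspF (-3.18 to -4.48 depending on the pseudocount), yiaD (to a mean of 44.11, -2.82 to -4.84) and rph, an exoribonuclease gene that is truncated in MG1655 (-2.88 to -4.18). By limma 457 genes rose and 307 fell of 3617 (1170 at an unadjusted p under 0.05), 442 and 291 of them at least 2-fold, while the median of all genes moved by 0.15. With array version as a block 484 rose and 326 fell, on the older arrays alone 383 and 200 (530 shared). Rises made up 59.8% of the calls, 47.2% after quantile normalization (399 rose and 446 fell) and 38.9% after median centring (340 and 535). On values as deposited the count was 283, and with the trimmed mean over each array's own probe sets it was 585 (582 shared). Of the 74 genes named for this span that passed, 56 passed without any one of the 12 arrays.

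From 90 to 360 minutes all 21 RpoS-dependent stress genes rose (21 adjusted over the list alone), with a median of 3.99, or 4.0 on the older and 3.65 on the newer arrays. They include yeaG (4.58 to 6.07 depending on the pseudocount), elaB (4.79), talA (4.78) and otsB (4.68). Camera called the list at adjusted p = 2.77e-20, and it had adjusted p = 0.0744 with an estimated correlation. Of 14 acid resistance genes 8 rose (10 adjusted over the list alone), among them hdeA (4.84), with a list median of 2.50. Of 4 hibernation genes 3 rose, sra, rmf and raiA (4.04), or 4 adjusted over the list alone. Camera gave these lists adjusted p = 8.68e-05 and 0.000186, or adjusted p = 0.557 and 0.283 with an estimated correlation. Of 15 TCA cycle genes 13 rose (15 adjusted over the list alone), with gltA at 3.75 and fumC at 2.63 to 4.12 depending on the pseudocount, and a list median of 2.24 (camera adjusted p = 5.61e-07, or adjusted p = 0.435 with an estimated correlation). The TCA count was 6 to 14 with each array left out in turn (6 without 360-minute replicate 1), and the TCA median was 3.42 on the older and 0.424 on the newer arrays.

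Of 28 iron genes 8 rose from 90 to 360 minutes (9 adjusted over the list alone), with entF up from a mean of 10.91 by 2.48 to 5.84, depending on the pseudocount, and a list median of 0.678. Of 68 sugar and glycerol genes 15 rose (16 adjusted over the list alone), with mglB at 4.55 and gatY, for galactitol, at 4.04 (list median 0.651). With each array left out in turn 11 to 20 rose and 0 to 2 fell (11 and 2 without 90-minute replicate 2). The median log2 signal of that list at 90 and 360 minutes was 7.56 and 8.64 on replicate 1, 7.32 and 8.46 on replicate 2, but 8.81 and 8.05 on replicate 3. Of 22 genes of amino acid breakdown 9 rose and 1 fell (9 and 1 adjusted over the list alone), with dadA at 4.17 next to astC (list median 0.746, or 0.48 without 360-minute replicate 1). Of 29 phosphate starvation genes 7 rose (7 adjusted over the list alone), with psiF at 4.42 and phoH at 2.08 to 3.28 depending on the pseudocount (list median 0.461). Camera gave these lists adjusted p = 0.000497, 0.0014, 0.0077 and 0.0264. None held: adjusted p = 0.435, 0.665, 0.435 and 0.665 with an estimated correlation. Of the phosphate genes 2 rose without 90-minute replicate 2 or 360-minute replicate 1. The phosphate call ended without 90-minute replicate 3 (0.0731) or 360-minute replicate 2 (0.0675).

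Of 54 ribosomal protein genes 30 fell from 90 to 360 minutes (38 adjusted over the list alone), with a median of -1.54. They include rpsT (-3.39, SE 0.57), rplI (-3.28, SE 0.70), rpsR (-3.03, SE 0.66) and rpmH (-2.82, SE 0.29). Camera called the list at adjusted p = 3.73e-19, and it had adjusted p = 0.394 with an estimated correlation. With each array left out in turn 20 to 39 ribosomal protein, 3 to 9 synthetase and 2 to 5 translation factor genes fell, the last being 2 without 90-minute replicate 1 or 360-minute replicate 1 or 3. Of 9 ATP synthase genes 6 fell (9 adjusted over the list alone), with atpH at -1.87 and a list median of -1.71. Of 15 purine genes 6 fell (8 adjusted over the list alone), with purB at -2.09 and prs at -1.93. Of 22 aminoacyl-tRNA synthetase genes 8 fell and 1 rose (13 and 1 adjusted over the list alone), with pheS at -1.86. Of 9 translation factor genes 4 fell (6 adjusted over the list alone), with prfC at -3.11 and infA at -2.59. Camera gave these lists adjusted p = 1.23e-05, 2.2e-05, 5.97e-05 and 0.000277, or adjusted p = 0.435, 0.283, 0.283 and 0.25 with an estimated correlation. Of 16 heat shock genes 2 fell, hslU (-1.54) and hslV (-1.30), also 2 adjusted over the list alone, with a list median of -0.754 (camera adjusted p = 0.0157, or adjusted p = 0.67 with an estimated correlation). The heat shock count was 0 without 90-minute replicate 1 and 1 without 90-minute replicate 3 or 360-minute replicate 1 or 3.

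Of 47 tRNA genes 7 fell from 90 to 360 minutes (7 adjusted over the list alone), with argX at -3.31 (SE 0.76) and leuW at -2.24 (SE 0.53), and the list median was -0.49 (camera adjusted p = 0.00204, or adjusted p = 0.672 with an estimated correlation). The median was -1.32 on the older and 1.07 on the newer arrays, where argX changed by 0.02 and leuW by -0.23. The count of 7 was 4 without 90-minute replicate 1 or 2 and 13 without 90-minute replicate 3, with medians of -0.301, -0.284 and -1.08. The list's call ended without 90-minute replicate 2 (0.182) or 360-minute replicate 2 (0.102, median -0.252) and after quantile normalization (0.126).

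**Figure D3:**
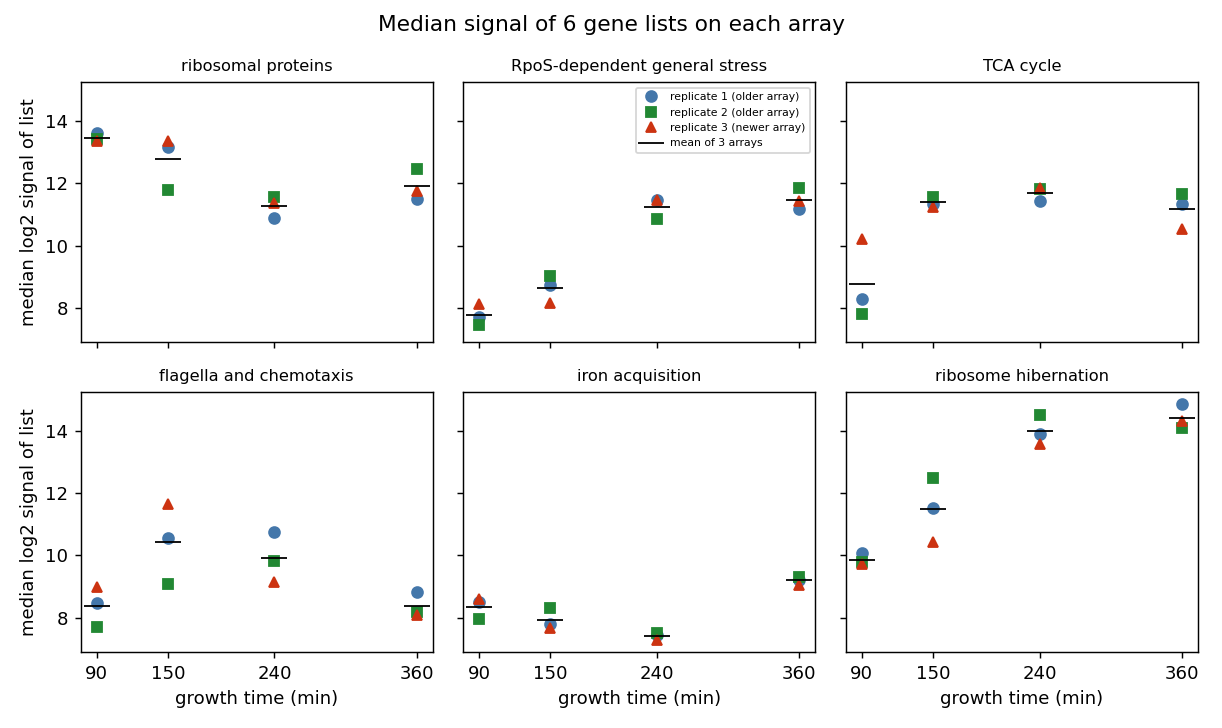
Median log2 signal over the members of 6 gene lists on each of the 12 arrays, by time in minutes, with marker shape for the replicate and bars for the mean of the 3 arrays. The iron acquisition list lies between 7.27 and 7.50 on the arrays of 240 minutes and between 9.06 and 9.32 on those of 360 minutes, and the RpoS-dependent list lies between 7.46 and 8.14 at 90 minutes and between 11.16 and 11.84 at 360.

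Among 14 genes of nucleoid proteins and topoisomerases, dps, ihfA and ihfB rose. From 90 to 360 minutes ihfA rose by 1.11 (SE 0.28) and ihfB by 1.38 (SE 0.31), the subunits of integration host factor, and parE of topoisomerase IV fell by 0.91 (log2 scale, SE 0.30, limma adjusted p = 0.047, a call that ended without any one of 9 of the 12 arrays, with 0.051 to 0.17). The histone-like genes hns (0.17), hupA (0.18) and hupB (-0.33), and gyrA (-0.72) and gyrB (-0.85) of DNA gyrase, did not pass in that span. The list itself was not called by camera in any comparison (adjusted p = 0.269 to 0.656). Among 11 genes of RNA polymerase and sigma factors, rpoE rose by 1.90 (SE 0.42), rpoS by 1.25 (SE 0.31), fecI by 1.05 (SE 0.33) and rpoN by 0.94 (SE 0.29) over the whole span, while rpoA (-1.57, SE 0.44) and rpoZ (-1.16, SE 0.29) fell. Of these whole-span calls only that of rpoE held without each array. Those of fecI, rpoN, rpoA, rpoZ and rpoS ended without any one of 6, 5, 4, 2 and 1 of the 12 arrays, with adjusted p up to 0.13, 0.13, 0.089, 0.058 and 0.055. From 90 to 150 minutes fecI and rpoZ fell, calls that ended without any one of 9 and 12 of the 12 arrays. From 150 to 240 minutes fecI fell by 0.81 to 1.80 depending on the pseudocount, a call that ended without any one of 7 arrays. It rose from 240 to 360 minutes by 2.84 to 4.40 depending on the pseudocount, and that call held without each array. The list of RNA polymerase and sigma factors was not called either (camera adjusted p = 0.0799 to 0.762).

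Further lists that camera did not call in any comparison were pyrimidine (adjusted p = 0.0813 to 0.81), arginine (0.18 to 0.768), histidine (0.0656 to 0.308) and branched-chain amino acid biosynthesis (0.319 to 0.962), the glyoxylate shunt with acetate uptake (0.303 to 0.688) and the SOS response (0.0656 to 0.768). From 90 to 360 minutes 2 of 7 glyoxylate shunt and acetate uptake genes and 2 of 14 SOS genes rose, and 1 of 9 pyrimidine genes rose and 2 fell. Of the arginine (9), histidine (8) and branched-chain (14) genes 0 passed limma in that span.

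Over the 4 times 931 of 3617 genes changed by limma's F test. Their highest mean was at 90 minutes for 323, at 150 for 75, at 240 for 292 and at 360 for 241. The most frequent time was 240 minutes without 90-minute replicate 1 or 240-minute replicate 2, on the older arrays alone and on values as deposited.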

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

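The tests on the fis signal, the TCA cycle list and the tRNA list below were chosen only after the results were seen. On the 4 newer arrays the probe set of a phage P1 cre reading frame, which no comparison uses, had deposited signals from 7476.4 to 14087.1, against 5592.4 to 13592.4 for the CreX spike control probe sets and at most 19.9 for 3 HXB2 control probe sets. The probe set of the other cre reading frame had at most 55.1. Whether the high cre signal came from the spike control rather than from the cells was not tested. Of 2886 intergenic probe sets, which only the newer arrays carry, 1325 (45.9%) lay above the highest HXB2 control on all 4 newer arrays.

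The fis signal of the array labelled 150 minutes replicate 3, 5697.2 after scaling, stood 11.6-fold above the highest of the other 11 arrays. At 90, 240 and 360 minutes the newer array also read fis above both older ones (scaled 492.3, 303.4 and 277.1, against at most 279.0, 235.3 and 264.2). A higher reading on the newer version is argued against as the whole source by those 3 arrays. There fis reached percentile 62.1 at most, against 96.2 here. A swap with another array of the series cannot be judged from the highest other scaled signal, 492.3. An exchange of labels within the series would also leave a single array with a high signal. RNA from cells with an intact fis gene remains a candidate explanation, for the whole sample or part of it. The series has no array labelled as from such cells to set the 11.6-fold against, which keeps it open.

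The TCA cycle genes changed less from 90 to 360 minutes on the newer arrays (median 0.42) than on the older ones (3.42). A compressed scale on the newer arrays is argued against by the RpoS-dependent list, whose median change there was 0.911 of that on the older arrays. A fixed log2 offset between the probe sets of the 2 versions would cancel in a change within a version, so it could not give this pattern. The TCA genes of replicate 3 deviated from replicates 1 and 2 by 1.95 at 90, -0.44 at 150, 0.10 at 240 and -0.84 at 360 minutes. Each gene's deviation at 90 minutes minus its mean at the other 3 times had a median of 2.11. These deviations restate the pattern and are no separate evidence. Whether the 90-minute culture of replicate 3 was as far along as the older 150-minute cultures stays open, because the lists differ. Of 25 RpoS-dependent and hibernation genes 22 rose more from 90 to 360 minutes on the newer arrays (median 3.70) than from 150 to 360 on the older ones (2.52), which goes against it. On the 90-minute array of replicate 3 the median log2 signal was 10.94 for the NADH dehydrogenase I and cytochrome bo oxidase list and 8.81 for sugars and glycerol, next to 10.92 and 10.19, and 8.48 and 8.85, on the older 150-minute arrays, which goes with it. The TCA median there, 10.22, lay between the older arrays of 90 minutes (8.30 and 7.81) and of 150 (11.35 and 11.56). No other biological explanation was tested, and any further difference between the cultures of replicate 3 and the others, confounded with array version, stays open.

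The tRNA genes moved in opposite directions from 90 to 360 minutes, with a median of -1.32 on the older and 1.07 on the newer arrays. The newer value rests on a single array at each time. The list's median log2 signal at 90 minutes was 12.71, 13.42 and 10.96 on replicates 1, 2 and 3. At 360 minutes it was 11.46, 10.48 and 11.41. Replicate 3 thus lay below both others at 90 minutes and between them at 360. Probes shared between tRNA genes are argued against as the whole source by the 18 probe sets without shared probes, which had medians of -1.54 and 1.30, next to -1.32 and 0.61 for the 29 with shared probes. Of the 47 genes 33 had opposite signs on the 2 versions. Array version and the culture of replicate 3 cannot be told apart, because replicate 3 alone is on the newer version. No biological explanation was tested.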

How the results depend on the processing

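The alternatives with array version as a block, the older arrays alone, the trimmed mean over each array's own probe sets, and the replicate block without the array labelled 150 minutes replicate 3 were chosen only after the data were seen. The results were 150 genes for 90 to 150 minutes, 292 for 150 to 240, 58 for 240 to 360, 764 for 90 to 360, 931 over the 4 times, 57 list calls (28 up and 29 down), 190 calls among named genes and 90 minutes as the most frequent time of the highest mean. On values as deposited the gene counts were 45, 111, 27, 283 and 394, the most frequent time was 240 minutes and 106 calls among named genes passed. A pseudocount of 1 gave 58 for 90 to 150 minutes and 28 for 240 to 360. With only the 6 arrays compared, and so fewer arrays behind the spread, the steps gave 14, 170 and 34 genes. The older arrays alone, again fewer, gave 109 for 150 to 240 minutes, 27 for 240 to 360, 126 calls among named genes and 240 minutes as the most frequent time. The trimmed mean over each array's own probe sets gave 56 for 90 to 150 minutes and 29 for 240 to 360. List calls numbered 1 with an estimated correlation and 30 with fry. Fry asks whether a list's members changed, not whether they differ from all other genes, and its values are given beside some lists only.

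Replicate numbers were not taken as pairs. Of 18 pairs of arrays with the same number 15 had deviations correlated above 0.1 (median 0.207, range 0 to 0.383, against -0.109 for different numbers), and 12 of 12 arrays were closest to their own number. Deviations are from the mean of the arrays of a time, so a positive same-number correlation pushes those for different numbers below 0. The -0.109 is thus no separate comparison. Replicate number as a block gave 218, 374, 59, 915 and 1087 genes, 57 list calls and 189 calls among named genes. The same block without the array labelled 150 minutes replicate 3 gave 233 for 90 to 150 minutes and 110 for 240 to 360. The flagella list from 150 to 240 minutes had a median of -1.04, against 0.02 (called upward by camera, adjusted p = 0.026) on the older arrays alone and -0.38 with that block and left-out array.

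Leaving out each array in turn gave 6 to 179 genes for 90 to 150 minutes, 184 to 360 for 150 to 240, 19 to 77 for 240 to 360, 555 to 820 for 90 to 360 and 664 to 980 over the 4 times. It gave 51 to 60 list calls, 127 to 170 calls among named genes, and 90 or 240 minutes as the most frequent time. Without 90-minute replicate 1 the counts were 6 for the first step and 33 for the third, and without 360-minute replicate 2 the third was 19. The median of the tRNA list from 90 to 150 minutes ranged from -0.74 to 0.22 (0.22 without 90-minute replicate 2) and that of the flagella list from 150 to 240 minutes from -1.49 to -0.45 (-0.49, with camera's direction turned, without the array labelled 150 minutes replicate 3).

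Over the other alternatives, single lists stayed on their side of the threshold in 1642 cases, lost the call in 126, gained it in 26 and turned in 2. For named genes these numbers were 3318, 368, 56 and 0. Direction was compared only where either fit gave a call, so the first number of each set includes results never called, whatever their direction. With single arrays left out, lists stayed on their side in 1361 cases, lost the call in 48, gained it in 29 and turned in 2. For named genes these were 3030, 417, 9 and 0. Apart from the smaller numbers of arrays noted above, the cause was not tested. Signals are given without detection calls, so how far low ones lie above background is unknown.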

Other observations

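The gene families described first, and their tests, were chosen only after the data were seen, while the counts over other splits were planned. Families were named by shared 3-letter symbols with at least 4 tested members outside the fixed lists, which gave 170 families and 680 camera tests. Only some of the called families are described. Others had smaller adjusted p, such as nap from 240 to 360 minutes (median -1.46, camera adjusted p = 2.76e-05, or 0.899 with an estimated correlation). All 5 suf genes, for assembly of iron-sulfur clusters, rose from 90 to 360 minutes, with sufD at 3.33 (SE 0.44, n = 3 per time) and a family median of 2.43, or 2.56 on the older and 1.93 on the newer arrays. Of 6 glg genes, for glycogen, 5 rose over the same span, with glgS at 4.31 (SE 0.37) and a median of 2.02. Of 6 usp genes, for universal stress proteins, 5 rose, with uspF at 3.21 (SE 0.37) and a median of 2.39. Of 4 acc genes, for the first step of fatty acid synthesis, 3 fell, with accC at -2.54 (SE 0.42) and a median of -2.01. Camera gave these families BH-adjusted p = 0.00136, 0.00176, 0.00233 and 0.00663. None held: adjusted p = 0.94, 0.899, 0.899 and 0.906 with an estimated correlation.

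From 150 to 240 minutes 4 of 5 dpp genes, for dipeptide transport, rose, with dppA at 3.16 (SE 0.51) and a family median of 1.71, or 0.971 on the older and 2.96 on the newer arrays. Of 5 lsr genes, for uptake and processing of autoinducer 2, 4 rose, with lsrF at 2.56 (SE 0.40) and a median of 2.20. From 240 to 360 minutes 3 of 7 nrd genes, for ribonucleotide reductases, rose, with nrdE at 2.56 (SE 0.50), nrdI at 2.35 (SE 0.42) and nrdH at 2.18 (SE 0.43), and a median of 1.03. Camera gave BH-adjusted p = 0.000869, 0.000137 and 0.0272 for these. None held: adjusted p = 0.94, 0.899 and 0.94 with an estimated correlation. Without the array labelled 150 minutes replicate 3 the dpp and lsr families had camera adjusted p = 0.00209 and 0.000255. In the step from 240 to 360 minutes camera called dpp, glg and usp downward, with medians of -1.55, -0.556 and -0.913 (adjusted p = 3.6e-05, 0.0173 and 0.012). With an estimated correlation these had camera adjusted p = 0.899, 0.981 and 0.899.

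Each comparison of 3 arrays with 3 allows 10 splits of the 6 arrays, too few for a share under 0.05. For 90 to 150 minutes 1 split, the real one, gave as many genes as its 150, and the highest other gave 1. The real values and the highest others were 292 and 0 for 150 to 240 minutes, 58 and 1 for 240 to 360, and 764 and 0 for 90 to 360. In every other split each group holds arrays of both times, so a difference between the times adds to its spread. Low counts in those splits are thus no measure of what chance would give. For the F test over the 4 times 1 of 100 regroupings of the 12 arrays, the real one, gave as many as 931 genes, and the highest other gave 347. These regroupings ignore that arrays of the same replicate number resemble each other. In a further test, chosen after the data were seen, times were shuffled only among the arrays of each replicate number. There 1 of 100 regroupings, the real one, gave as many as 931 genes, and the highest other gave 351. A chance arrangement of times is thus unlikely under both schemes, within the limit of 100 regroupings each.

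Genes that lay more than 2 log2 units from the mean of the other arrays of their time, and beyond both of them, numbered 17, 44 and 75 on the arrays of 90 minutes (replicates 1, 2 and 3), 25, 99 and 94 at 150, 170, 38 and 65 at 240, and 25, 31 and 21 at 360.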
